A study of Mus musculus with 25 samples.

How the data were processed

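RNA from 25 mouse embryo samples was hybridised to Illumina MouseRef-8 v2.0 bead arrays, 1 sample to an array. The embryos carried a knockout (KO) of miR-302, a microRNA cluster of early embryonic cells, or were wild type (WT), all on a B6 background per the labels. Per the labels, the tissue was the whole embryo at embryonic day 7.5 (E7.5) and anterior neural tissue at E8.0, E8.5 and E9.5, except that replicate 1 of the E8.0 WT samples was labelled as a whole embryo. The series design text states that replicates were separate embryos. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on miRNeasy micro columns with DNase, checked on a Bioanalyser and amplified to biotin-labelled cRNA with the Ambion MessageAmp kit. Each array carried a plate label from 1 to 4.

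The deposited raw table held, per the file headers, an average signal and a detection p-value for each of 25697 probes on each array. The signal is an intensity on a linear scale without normalization, per the file headers. How the authors obtained the detection p-values is not given in the sources used here. They moved in steps of 1 in 798. The deposited series matrix held the authors' processed intensity values on a linear scale. In those values the arrays of E7.5 to E8.5 shared 1 distribution, with a median of 124, and the E9.5 arrays another, with a median of 153, as quantile normalization of each set on its own gives. The tools behind that table are not given in the sources used here.

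The 2 deposited tables disagree on the identity of 3 arrays. For the E8.0 WT arrays, the matrix column of replicate 1 ranked the probes as the raw column of replicate 3 did, that of replicate 2 as raw replicate 1 and that of replicate 3 as raw replicate 2. The other 22 columns matched their own raw signals, with a rank correlation of 1 for every best match. Which table carries the right identities is unknown. The raw table was used throughout, and the identity given by the matrix was run as an alternative chosen after seeing the data.

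Raw signals were background corrected with the normexp model, with the background distribution inferred from the detection p-values, quantile normalized and put on a log2 scale with an offset of 16 (the neqc function of limma 3.58.1 in R 4.3.3). A probe was kept where its detection p was under 0.05 on at least 3 arrays, which left 15030 probes. Probes were named by the platform annotation. Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. The Entrez identifiers of 23962 named probes were found in the RefSeq gene table (assembly GRCm38.p6), 16 were not, and 0 symbols needed an update. Of the kept probes, 885 had no symbol and were left out. For each gene the probe with the highest mean log2 value over all arrays was used, which gave 10261 genes, 2752 of them with more than 1 kept probe. No genome build is named in the sources used here, so no coordinates are given, and the RefSeq table served only for names and for the order of neighbouring genes.

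All 25 arrays entered 1 linear model with a coefficient for each of 9 groups, fitted with lmFit and eBayes (limma). The E8.0 WT array labelled as a whole embryo formed its own group and stayed outside the E8.0 comparison. The fit had 16 residual degrees of freedom, and 19.3 with the prior. Contrasts were KO minus WT at each stage, WT neural tissue between stages, and the difference of the KO minus WT contrasts between stages. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene passed at an adjusted p under 0.05. Every adjusted p of a gene below comes from limma. Values are log2 differences with their standard error (SE). Where a gene was above background on no array of a group, its fold is a bound. The mean of the brighter group is set against the dimmer group's mean of, per array, the higher of the gene's own value and the lowest value of a detected probe. No fold is given where neither group was above background. Nor is a bound given where the dimmer group is the E8.0 WT arrays, since their lowest detected value lay at the level of undetected genes.

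For sets, 29 gene lists were written from textbook knowledge of the tissue, of miR-302 and of other cell types the dissections could hold. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a stage. Camera was also run with an estimated correlation, and fry (limma) as a test without a background of other genes. Counts of list members that passed are given over all genes tested and adjusted over the list alone. The KO effect was also set against the WT change between the neural stages that share no arrays with it, as Pearson's correlation across genes. Its p is exact, from all relabellings of the stage's KO and WT arrays.

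Genes named in the text followed a rule. Per KO comparison, these were the 10 largest rises and the 10 largest falls among genes that passed, without sex-linked genes. Where fewer than 5 passed in a direction, genes of smallest p filled the number up to 5. To these came up to 4 members of each called list with the smallest p in its direction. Larp7, Fgf15, Cdkn1a, Lats2, Lefty1, Lefty2, Neurog2, Sox1, Pax6, Tubb3 and Hes5 were given at every stage. For WT time comparisons and differences between stages, these were the 5 largest in each direction. Predicted genes, Rik clones and LOC symbols were counted but passed over. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

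The number of arrays limits the precision. Raw signal over background also differed: the median raw signal per array was 107 to 148 from E7.5 to E8.5 and 222 to 262 at E9.5. In these ranges 42.5 to 47.5% and 50.2 to 53.0% of probes were detected. The scripts were tested on simulated data with known changes in these 10261 genes. Of genes changed 2-fold, 51% were recovered in the E7.5 comparison, 52% at E8.0, 65% at E8.5 and 73% at E9.5. Of genes changed 1.41-fold, 2%, 18%, 14% and 29% were recovered. Of the calls, 3.64%, 7.89%, 10.2% and 4.42% were false. The simulated noise was independent, with 1 spread per gene for all arrays and no plate effect. These rates therefore need not hold for the real comparisons, where arrays and plates differ.

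Alternatives covered the normalization (quantile on raw log2 signals, the series matrix values, median scaling, E9.5 arrays normalized on their own), the probe filter, the probe choice, the plate, array weights, the eBayes settings, a replicate block, each stage fitted alone, the E8.0 whole-embryo array, the threshold and each array left out in turn. Plate was used as a fixed covariate, as a random block and by comparing arrays within 1 plate. All E9.5 arrays, and no others, were on plate 4, so for WT comparisons with E9.5 the stage and the plate cannot be told apart. The WT neural arrays of E8.0 were on plate 1 and those of E8.5 on plate 2, so that comparison runs across plates as well. 0 pairs of arrays held identical signals. Target sites in transcript sequences were not analysed here. Figures were drawn with matplotlib 3.10.9.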

Results

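The arrays measured gene expression around the closing of the neural tube in embryos with and without miR-302. At E7.5 there were 3 KO and 2 WT whole embryos. Anterior neural tissue was profiled from 3 KO and 2 WT embryos at E8.0, 3 KO and 3 WT at E8.5, and 4 KO and 4 WT at E9.5. A further E8.0 WT array, labelled as a whole embryo, entered no comparison of the KO with WT. Arrays of 1 group correlated at 0.962 to 0.995 across probes. Across all arrays, the first principal component held 47.2% of the variance and the second 17.3%.

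No probe of the array measures the deleted microRNAs. Mir302a, Mir302b, Mir302c, Mir302d and Mir367 lie inside Larp7 in the RefSeq annotation, and the probe of Larp7, which encodes a 7SK RNA binding protein, was detected on 0 of 25 arrays (lowest detection p 0.183). The genotype labels therefore had no check in these data. Lats2, Lefty1 and Pax6 were detected on 0, 1 and 0 of the arrays, fewer than the 3 needed, and were not tested.

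The E7.5 comparison asked what differed in whole embryos before anterior neural tissue was taken. In KO embryos (n = 3) Bcl11a, a zinc finger transcription factor of neurons and lymphocytes, was at least 2.71-fold higher than in WT embryos (n = 2), with a log2 difference of 1.90 (SE 0.25, adjusted p = 0.00229). Scg5, a neuroendocrine chaperone, was at least 1.98-fold higher (1.89, SE 0.288, adjusted p = 0.00426), and the neuronal deubiquitinase Uchl1 was 2.69-fold higher (1.43, SE 0.207, adjusted p = 0.00408). Ugt8a, which makes galactolipids of myelin and is the 4th gene from Larp7 on 1 side, was 3.41-fold higher (1.77, SE 0.267, adjusted p = 0.00426). Lgr5, a receptor for R-spondins, was at least 2.14-fold lower (-1.39, SE 0.213, adjusted p = 0.00426).

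Of 10261 genes, 18 were higher and 5 lower in the E7.5 KO. The other large rises were Cavin3, a caveolar coat protein (3.21-fold), Zfp385a (at least 2.42-fold), the vesicular nucleotide transporter Slc17a9 (at least 1.6-fold), the mitochondrial factor Mterf2 (at least 1.36-fold), Tbc1d2 (2.35-fold) and Astn1, which acts in neuronal migration (2.35-fold), with adjusted p between 0.00408 and 0.0331. The other falls were the retinol receptor Stra6 (-1.63, SE 0.336, adjusted p = 0.0465), the DNA damage kinase Atm (-1.36, SE 0.256, adjusted p = 0.03), the nuclear exonuclease Xrn2 (-1.26, adjusted p = 0.0444) and the collagen receptor Mrc2 (-0.94, adjusted p = 0.0331). Other probes of Cavin3 (0.30), Mterf2 (0.31), Atm (-0.93), Xrn2 (0.17) and Mrc2 (0.53) did not pass, and those of Xrn2 and Mrc2 had the opposite sign. Fgf15 (0.28, adjusted p = 0.827), Cdkn1a (0.44, adjusted p = 0.738), Lefty2 (1.72, SE 0.493, adjusted p = 0.25), Sox1 (0.20) and Hes5 (0.12) did not pass at E7.5. Neurog2 (-0.10) and Tubb3 (0.09) were not above background in either group.

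Camera called 5 of the 29 lists at E7.5, and 0 of them with an estimated correlation. The 11 measured trophoblast and placenta genes were higher in the KO as a set (median 0.76, adjusted p = 0.00125, adjusted p = 0.393 with an estimated correlation), although 0 passed singly. Among these, Ascl2, a trophoblast regulator, was at 0.90, the prolactin relative Prl4a1 at 2.42 (SE 1.01), Plac1 at 0.94 and Tfap2c at 0.68. Of 32 neuronal differentiation genes 25 had positive values (median 0.17, adjusted p = 0.023, adjusted p = 0.393 with an estimated correlation). None passed over all genes and 2 did adjusted over the list alone, and Ebf1 (0.86), Insm1 (1.06), Stmn3 (1.13) and Gap43 (0.63) had the smallest p.

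As sets, 3 lists were lower in the E7.5 KO. Posterior Hox and axial progenitor genes had a median of -0.39 over 20 genes (adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation). Hoxb7 was at -1.02, Hoxa5 at -1.40, the retinoic acid hydroxylase Cyp26a1 at -0.61 and Fgf8 at -0.39, and 0 members passed. FGF pathway genes had a median of -0.17 over 21 genes (adjusted p = 0.035, adjusted p = 0.393 with an estimated correlation). Fgfbp3 was at -1.39, Etv4 at -0.49, Spry1 at -0.50 and Dusp4 at -0.42, and 0 passed. Of 27 Wnt pathway genes (median -0.17, adjusted p = 0.023, adjusted p = 0.393 with an estimated correlation) Lgr5 alone passed, over all genes and adjusted over the list alone. Nkd2 (-0.53), Sp5 (-0.48) and Axin2 (-0.38) did not. The adjusted p of the other 24 lists lay between 0.0854 (surface ectoderm and epithelium) and 0.885 (endothelium).

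KO replicate 1 was on plate 2 and the other E7.5 arrays on plate 1, and of the 15 named genes that passed, 8 did so with plate as a covariate, 15 with plate as a random block and 8 within plate 1. The posterior Hox, FGF and Wnt lists lost their calls with plate as a covariate (adjusted p = 0.245, 0.179 and 0.24), and the neuronal and trophoblast lists within plate 1 (adjusted p = 0.0812 and 0.139). Without WT replicate 1 the count of genes was 60, without KO replicates 1, 2 and 3 it was 11, 12 and 37. With E7.5 fitted alone 0 genes passed (limma), against 23 in the shared fit, where 817 had an unadjusted p under 0.05. The calls thus rest on a spread pooled over all stages.

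At E8.0, anterior neural tissue of KO embryos (n = 3) had less Sema4f, a semaphorin of the nervous system, than WT tissue (n = 2), 4.56-fold lower (-2.19, SE 0.432, adjusted p = 0.0258). Ccng1, a p53-induced cyclin, was 2.73-fold higher (1.45, SE 0.249, adjusted p = 0.0185). So were the G protein subunit Gng5 (3.37-fold, SE 0.35 on the log2 scale, adjusted p = 0.0263) and Sdhd, a membrane anchor of succinate dehydrogenase (3.12-fold, SE 0.249, adjusted p = 0.0185). Hand1, a transcription factor of heart, extraembryonic mesoderm and trophoblast, was 2.58-fold higher (1.37, SE 0.253, adjusted p = 0.0185). The ventral neural gene Nkx2-2 (at least 2.12-fold, adjusted p = 0.0309) and the patterning gene Irx1 (4.04-fold, adjusted p = 0.0363) were lower.

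Of 10261 genes, 123 were higher and 55 lower in the E8.0 KO. Among the other named rises Ap1s3 was at 1.54, without a fold as it was not above background in WT tissue, and Golt1a at 1.58. With them rose the microtubule regulator Stmn3 (2.84-fold), the epiblast gene Utf1 (2.68-fold), the DNA repair gene Xrcc4 (2.63-fold) and Tomm70a, a mitochondrial import receptor (2.59-fold). The adjusted p of all these ran from 0.0363 to 0.0494. The other named falls were the matrix genes Thbs2 (at least 1.83-fold) and Prelp (at least 1.92-fold), the amine oxidase Aoc3 (at least 1.97-fold), Pik3ip1 (at least 1.72-fold), Uck1 (3.45-fold), Rbm14 (2.89-fold) and the actin regulator Cttn (2.8-fold), with adjusted p from 0.0185 to 0.044. Other probes of Ap1s3 (0.36), Nkx2-2 (-0.03), Uck1 (-0.11 to -0.86), Cttn (-0.16 to -0.70) and Rbm14 (0.20, the opposite sign) did not pass, and of the 2 other Ccng1 probes (1.03 and 0.96) 1 did.

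Fgf15, a growth factor of the neural tube, was 1.89-fold higher at E8.0 without passing (0.92, SE 0.246, adjusted p = 0.0585), and within plate 1 it passed (1.10, adjusted p = 0.0334). Over its 23 alternatives the adjusted p ran from 0.0112 to 0.404. Cdkn1a, which encodes the cell cycle inhibitor p21 and is a reported miR-302 target, did not pass (0.64, adjusted p = 0.188), although of its other probes (0.56 and 1.15) 1 did. Nor did the Notch effector Hes5, at -1.14 (SE 0.474, adjusted p = 0.192), with Neurog2 at 0.19, Tubb3 at 0.35, Sox1 at -0.09 and Lefty2 at -0.30.

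Of the lists, 2 were called at E8.0 and 0 with an estimated correlation. The 26 neural progenitor genes were lower as a set (median -0.35, adjusted p = 0.035, adjusted p = 0.927 with an estimated correlation). None passed over all genes and 1, Hes3 (-1.59, adjusted p = 0.0559), did adjusted over the list alone, with Sox2 at -1.35, Cntfr at -0.72 and Mfge8 at -0.46. On KO replicate 1 this list had a mean log2 signal of 7.27, against 7.89 and 7.99 on the other KO arrays and 8.06 and 8.09 on the WT arrays. Pluripotency and epiblast genes had a mean of 9.12 there, against 7.58 to 7.89 on those arrays. All 11 trophoblast and placenta genes had positive values (median 0.74, adjusted p = 0.035, adjusted p = 0.927 with an estimated correlation). Hand1 passed, over all genes and adjusted over the list alone, and Plac8 (1.33), Tfap2c (0.74) and Peg10 (0.47) did not. The adjusted p of the other 27 lists ran from 0.0599, for Shh pathway and ventral patterning genes (median -0.71), to 0.871.

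With the authors' series matrix values 7 genes were higher and 9 lower at E8.0. With the array identities of the series matrix 4 genes passed, of the named ones Ccng1 (1.42, adjusted p = 0.0385) and Sema4f (-2.51, adjusted p = 0.0385), and the trophoblast list was lost (adjusted p = 0.451). With the whole-embryo array added 31 genes passed, of the named ones Stmn3, Ccng1, Sema4f, Nkx2-2 and Cttn, and the trophoblast list was lost (adjusted p = 0.116). With plate as a covariate 53 genes passed, 8 of the 20 named ones among them, and the neural progenitor list was lost (adjusted p = 0.21). Without WT replicates 2 and 3 the counts were 0 and 14, without KO replicates 1, 2 and 3 they were 27, 54 and 695. With E8.0 fitted alone 0 genes passed (limma), against 178 in the shared fit, where 2039 had an unadjusted p under 0.05. These calls too rest on the pooled spread.

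At E8.5, anterior neural tissue of KO embryos (n = 3) had 2.85-fold more Neurog2, a proneural transcription factor that lies close to Larp7, than WT tissue (n = 3), with a log2 difference of 1.51 (SE 0.275, adjusted p = 0.00509). The neuronal microtubule regulator Stmn3 was 5.37-fold higher (2.42, SE 0.342, adjusted p = 0.00117). Cdkn1a was 2.72-fold higher (1.44, SE 0.236, adjusted p = 0.00255) and Fgf15 1.89-fold higher (0.92, SE 0.22, adjusted p = 0.0229). The Wnt ligand Wnt7a was at least 2.41-fold higher (2.14, SE 0.266, adjusted p = 0.000693) and the Wnt agonist Rspo3 5.34-fold higher (2.42, SE 0.333, adjusted p = 0.00117). Foxd4, a forkhead gene of early neural ectoderm, was 10.5-fold lower (-3.39, SE 0.515, adjusted p = 0.00163).

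Of 10261 genes, 326 were higher and 248 lower in the E8.5 KO. The other named rises were the muscle gene Myl1 (at least 3-fold), Smpdl3a (at least 2.59-fold), the ectonucleotidase Nt5e (3.78-fold), the histone gene H2bc8 (3.76-fold), Rpl22l1 (3.6-fold), the forebrain homeobox gene Dlx1 (3.44-fold) and Gdap1 (3.18-fold), with adjusted p from 0.00343 to 0.0267. The other named falls were Bcas1, a gene of myelinating cells (6.29-fold), the Wnt modulator Dact2 (4.84-fold), Sema4f (4.13-fold), Vstm2l (3.91-fold), the haem oxygenase Hmox1 (at least 2.28-fold), the glycolytic gene Pfkp (3.79-fold), the GABA transporter Slc32a1 (3.35-fold), Laptm5 (3.32-fold) and Elfn1 (3.22-fold), with adjusted p from 0.000281 to 0.0479. Values of single KO and WT embryos overlapped for Slc32a1. Other probes of Neurog2 (0.48) and Pfkp (-0.83) did not pass, and of those of Cdkn1a (0.82 and 0.56) 1 did. Sox1 (-0.43), Tubb3 (-0.08), Hes5 (-0.13, adjusted p = 0.888) and Lefty2 (-0.02) did not pass.

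By list, 5 of 32 neuronal differentiation genes rose and 1 fell at E8.5 (6 and 1 adjusted over the list alone), but the list was not called (adjusted p = 0.224). Of 22 reported miR-302 or seed-family targets 4 rose and 1 fell, with the same numbers adjusted over the list alone (list adjusted p = 0.338). Of 21 FGF pathway genes 3 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.674). Camera called surface ectoderm and epithelium genes as higher (16 genes, median 0.43, adjusted p = 0.0424, adjusted p = 0.91 with an estimated correlation). Of these the tight junction gene Cldn3 passed, over all genes and adjusted over the list alone (1.34, SE 0.361, adjusted p = 0.0358), and Wnt6 (0.55), Cdh1 (0.53) and Trp63 (1.13) did not. The list's mean log2 signal was 9.37 and 9.41 on KO replicates 2 and 3 and 8.80 on KO replicate 1, against 8.63 to 9.03 on the WT arrays. The adjusted p of the other 28 lists ran from 0.0976, for endothelium (14 of 15 genes negative, median -0.52), to 0.959.

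The E8.5 WT arrays and KO replicate 1 were on plate 2 and KO replicates 2 and 3 on plate 3. With plate as a covariate, as a random block and within plate 2, the counts were 99, 223 and 170 genes, and the surface ectoderm list was lost (adjusted p = 0.953, 0.18 and 0.856). Plate 2 held 1 KO array, whose spread was taken from the other groups. Plate 3 held no arrays but KO replicates 2 and 3, so with plate as a covariate the KO effect also came from KO replicate 1 alone. The first and last settings are thus the same comparison and not separate support. Stmn3, Rspo3, Wnt7a, Foxd4, Bcas1, Dact2, Sema4f, Vstm2l and Elfn1 kept their calls in all 3 settings. The random block adds KO replicates 2 and 3 to the same WT arrays and KO replicate 1, so it is not separate support either. Fgf15 lost its call in all 3 (adjusted p = 0.183, 0.0542 and 0.0849), Cdkn1a in the first and last (adjusted p = 0.0768, 0.0108 and 0.0795) and Neurog2 in the first (adjusted p = 0.0513, 0.0128 and 0.0486). With plate as a covariate the values of these 3 genes were 0.94 (SE 0.325), 1.22 (SE 0.322) and 1.64 (SE 0.384), so the calls ended with the wider errors and, for Cdkn1a, a smaller value. Over the 21 alternatives the adjusted p of these 3 genes ranged from 0.0073 to 0.183, from 0.000943 to 0.157 and from 0.0038 to 0.237. Without WT replicates 1, 2 and 3 the counts were 110, 370 and 319, without KO replicates 2 and 3 they were 141 and 264. With E8.5 fitted alone 0 genes passed (limma), against 574 in the shared fit, where 2360 had an unadjusted p under 0.05. The E8.5 calls thus rest on the pooled spread as well. That pool includes the E9.5 arrays, which were more alike within groups (lowest correlation 0.984, against 0.974 at E8.5). The SE given for the earlier stages may therefore be too small.

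**Figure D1:**
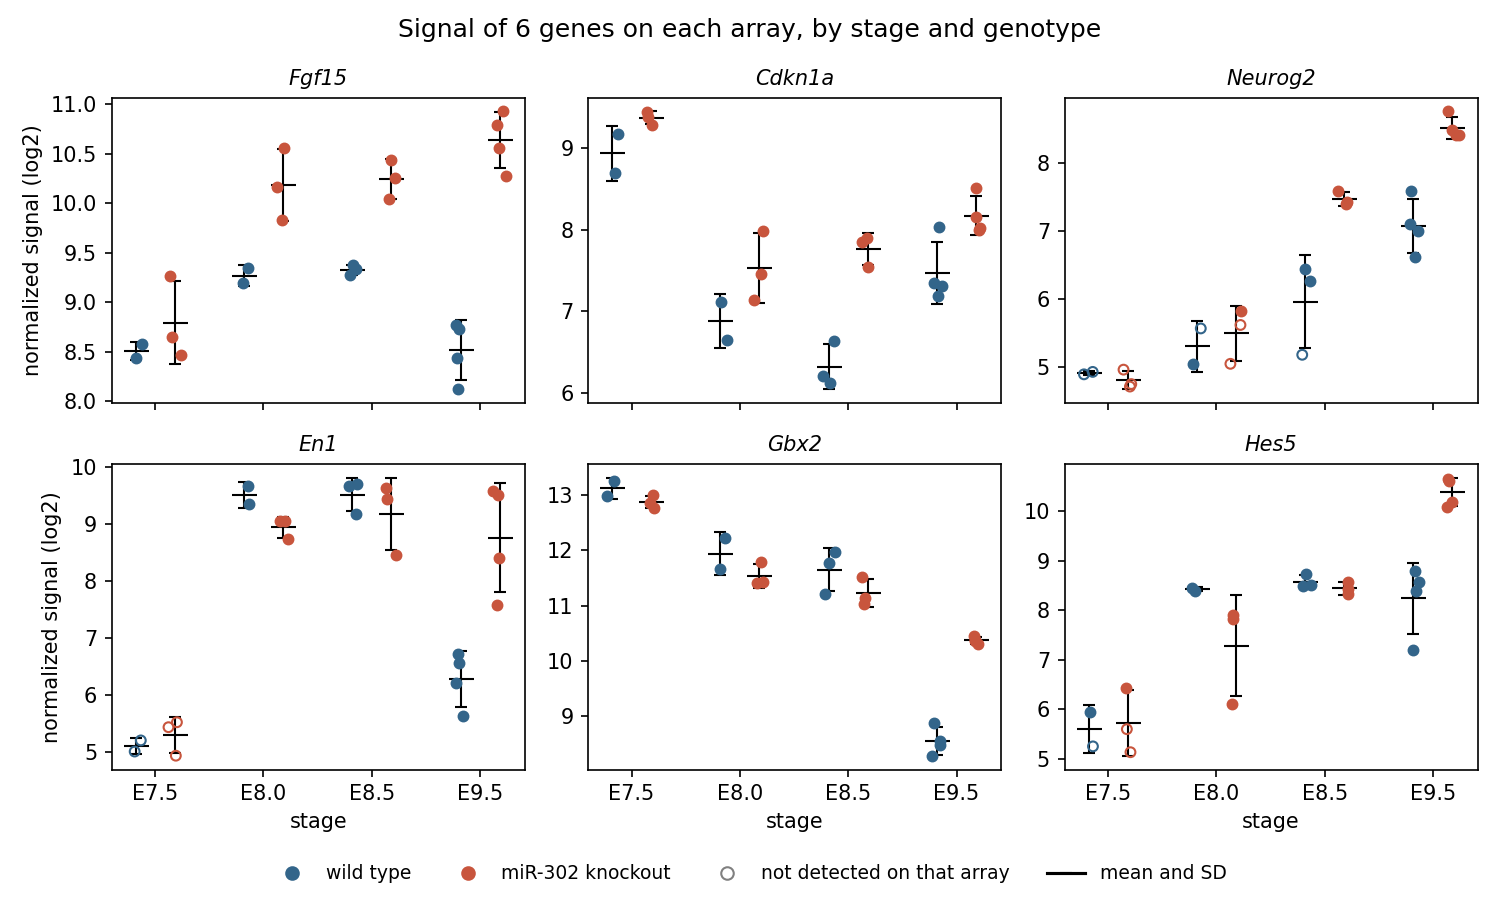
Log2 signal of Fgf15, Cdkn1a, Neurog2, En1, Gbx2 and Hes5 on each array by stage, with WT in blue, KO in red, hollow points for arrays on which the gene was not detected, and bars for the mean and SD of each group. The KO and WT arrays separate for Fgf15 at E9.5, where the KO mean is 10.64 and the WT mean 8.52.

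At E9.5, genes of the midbrain and the isthmus, the signalling centre between midbrain and hindbrain, were higher in anterior neural tissue of KO embryos (n = 4) than of WT embryos (n = 4). The homeobox genes En1 and En2, which pattern this region, were 5.57-fold (2.48, SE 0.358, adjusted p = 0.000891) and 5.45-fold higher (2.45, SE 0.515, adjusted p = 0.0172). Fgf15 was 4.37-fold higher (2.13, SE 0.191, adjusted p = 7.37e-06), Gbx2, which marks the anterior hindbrain, 3.52-fold (1.82, SE 0.169, adjusted p = 7.37e-06) and Wnt1, a ligand of the midbrain border, 2.95-fold (1.56, SE 0.174, adjusted p = 6.7e-05). The progenitor gene Hes5 was 4.44-fold higher (2.15, SE 0.367, adjusted p = 0.00362), while the forebrain genes Dmrt3 and Wnt8b were 2.45-fold and 2.2-fold lower (adjusted p = 0.0414 and 0.0256).

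Of 10261 genes, 160 were higher and 73 lower in the E9.5 KO. The other large rises were Hes3 (at least 2.84-fold, adjusted p = 0.00434), the collagen receptor Ddr1 (3.52-fold, adjusted p = 0.0389), the planar polarity cadherin Celsr2 (3.23-fold, adjusted p = 0.0147), Wnt7a (3.12-fold, SE 0.23, adjusted p = 0.000725) and Fgfbp3 (3.04-fold, adjusted p = 0.0356). Neurog2 was 2.71-fold higher (1.44, SE 0.238, adjusted p = 0.00289), although its other probe was at -0.12, and the other probes of Hes5 (2.06), Ccnd1 and Fzd10 passed too. The other probes of Sox21 (1.18), Syt11 (0.88 and 0.47), Nkx2-9 (0.87), Nkx2-2 (0.57), Dusp4 (0.17 and 0.55) and Irx2 (0.33) did not pass. The largest falls were the protease inhibitor Spink1 (4.74-fold), the amino acid transporter Slc38a8 (3.29-fold), the sterol transporter Abcg5 (2.87-fold), the imprinted gene Phlda2 (2.74-fold), the retinoic acid enzyme Aldh1a3 (2.5-fold), Inmt (2.48-fold), Dmrt3, the photoreceptor cadherin Cdhr1 (2.3-fold), Tinag (2.25-fold) and the carbonic anhydrase Car4 (2.2-fold), with adjusted p from 0.000543 to 0.0414. Single KO and WT embryos overlapped for Spink1, Hoxb2 and Pou3f3. Cdkn1a was 1.62-fold higher without passing (0.70, SE 0.204, adjusted p = 0.0781), and Sox1 (0.33), Tubb3 (-0.05) and Lefty2 (-0.05) did not pass either.

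The lists of regional genes asked where along the neural tube the E9.5 changes lay. Of 11 midbrain and isthmus genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.73, adjusted p = 1.11e-07), and this was the single list also called with an estimated correlation (adjusted p = 0.019). The isthmus genes Fgf8 (0.17), Fgf17 (0.73) and Lmx1b (-0.00) did not pass, and these were picked outside the naming rule, after their values were seen. All 13 hindbrain genes had positive values, and 3 rose (5 adjusted over the list alone, median 0.48, adjusted p = 2.69e-06, adjusted p = 0.0536 with an estimated correlation). These were Gbx2, Irx2 (1.98-fold, SE 0.163, adjusted p = 0.00284) and Hoxb2 (2.26-fold, adjusted p = 0.0415), with Hoxa2 at 1.17 (adjusted p = 0.0506). Of 14 forebrain genes 13 had negative values and 2 fell (3 adjusted over the list alone, median -0.47, adjusted p = 0.000476, adjusted p = 0.195 with an estimated correlation). These were Six3, at least 1.45-fold lower (adjusted p = 0.0227), and Wnt8b, and Dmrta2 (-1.17) and Nkx2-1 (-0.84) did not pass.

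**Figure D2:**
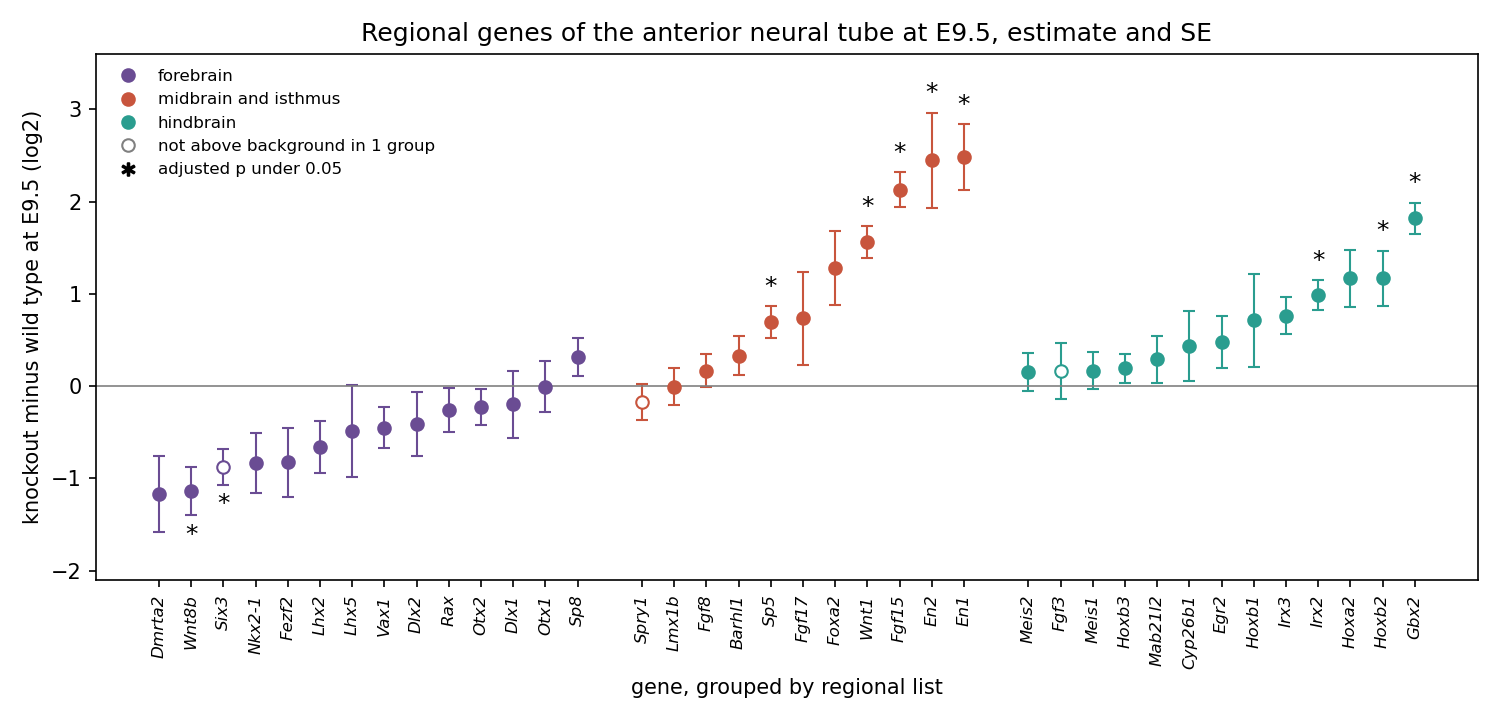
Log2 difference between KO and WT at E9.5, with SE bars, for 14 forebrain, 11 midbrain and isthmus and 13 hindbrain genes, with a star at an adjusted p under 0.05 and hollow points for genes above background in only 1 of the 2 groups. En1 (2.48) and En2 (2.45) lie highest, and the forebrain gene Dmrta2 at -1.17.

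Progenitor and signalling lists were higher as sets in the E9.5 KO, each losing its call with an estimated correlation. Of 26 neural progenitor genes 4 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.44, adjusted p = 4.95e-05, adjusted p = 0.15 with an estimated correlation). Sox21 was 2.43-fold (SE 0.247, adjusted p = 0.00884) and Pou3f3 1.88-fold higher (adjusted p = 0.0312). Of 16 Notch pathway genes 15 had positive values and 2 rose (5 adjusted over the list alone, median 0.31, adjusted p = 7.54e-05, adjusted p = 0.0536 with an estimated correlation). These were Hes5 and the ligand Dll1 (2.19-fold, adjusted p = 0.0114), with Nrarp at 0.88 and Notch1 at 0.76. Of 21 FGF pathway genes 5 rose, over all genes and adjusted over the list alone (median 0.17, adjusted p = 0.000174, adjusted p = 0.0536 with an estimated correlation). Among them were Fgf15, the receptor Fgfr3 (2.63-fold, adjusted p = 0.0226) and Dusp4 (1.8-fold, adjusted p = 0.0112). Of 27 Wnt pathway genes 6 rose and 1 fell (8 and 3 adjusted over the list alone, median 0.14, adjusted p = 0.0266, adjusted p = 0.165 with an estimated correlation). The rises included Wnt3a (2.56-fold), the receptor Fzd10 (1.74-fold) and Sfrp2, a secreted Wnt inhibitor (2.44-fold).

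Of 11 Shh pathway and ventral patterning genes Nkx2-9 (2.16-fold, adjusted p = 0.014) and Nkx2-2 (2.27-fold, adjusted p = 0.0445) rose (4 rose and 1 fell adjusted over the list alone, median 0.29, adjusted p = 0.0298, adjusted p = 0.334 with an estimated correlation). Foxa2 was at 1.28 and Nkx6-1 at 1.29. Of 32 neuronal differentiation genes 2 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.045, adjusted p = 0.263 with an estimated correlation). The rises were Neurog2 and Syt11 (1.91-fold), with Crmp1 at 0.77 and Stmn4 at 0.60. The list of 22 reported targets includes Fgf15 because of work on such mice, and so is not independent evidence. Of these, Fgf15 and the cyclin gene Ccnd1 (1.73-fold, SE 0.176, adjusted p = 0.0227) rose (5 adjusted over the list alone, median 0.08, adjusted p = 0.0414, adjusted p = 0.107 with an estimated correlation). Klf13 was at 0.59. Of 11 genes near the miR-302 locus Neurog2 rose (2 adjusted over the list alone, median 0.17, adjusted p = 0.0474, adjusted p = 0.195 with an estimated correlation). Pla2g12a was at 0.41, Ank2 at 0.39 and Gar1 at 0.33.

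Lists of other cell types and of metabolism also moved at E9.5. Of 18 hypoxia and glycolysis genes hexokinase Hk2 (1.83-fold, SE 0.173, adjusted p = 0.0114) and the glucose transporter Slc2a1 (1.58-fold, adjusted p = 0.0329) rose (5 adjusted over the list alone, median 0.46, adjusted p = 6.66e-05, adjusted p = 0.334 with an estimated correlation). Vegfa was at 0.86 and Egln1 at 1.07. Surface ectoderm and epithelium genes were lower as a set (16 genes, 0 passed and 3 fell adjusted over the list alone, median -0.33, adjusted p = 0.000204, adjusted p = 0.218 with an estimated correlation). Krt18 was at -0.59, Dlx3 at -0.57, Spint1 at -0.49 and Cldn6 at -0.48. So were primitive and definitive blood genes (13 genes, 0 passed and 1 fell adjusted over the list alone, median -0.34, adjusted p = 0.0182, adjusted p = 0.439 with an estimated correlation). Car2 was at -0.70, Klf1 at -0.74, Epor at -0.62 and Blvrb at -0.52. The lists not called, with their adjusted p, were head and trunk mesenchyme (0.061), trophoblast and placenta (0.0905), handling stress and immediate early genes (0.119), primitive streak (0.172), endothelium (0.185), cell cycle (0.211), the BMP, Nodal and TGF-beta pathway (0.276) and pluripotency (0.295). Visceral endoderm (0.388), neural tube closure (0.495), posterior Hox (0.517), neural crest (0.644), sex-linked genes (0.764), p53 targets (0.801) and cardiac genes (0.965) were not called either.

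All E9.5 arrays were on plate 4, so plate could not separate the groups there. With plate as a covariate in the shared fit, camera no longer called the reported targets (adjusted p = 0.0528), the genes near the miR-302 locus (0.0624) or neuronal differentiation (0.0528). With the E9.5 arrays normalized separately camera no longer called the first 2 of these (adjusted p = 0.0601 and 0.0791). With the authors' series matrix values 340 genes were higher and 270 lower, with the E9.5 arrays normalized separately 311 and 207, and with array weights 786 and 802. Without WT replicate 4, which lay apart for several of these genes, 62 genes passed and 13 of the 40 named calls were kept (En1, Hes5, Fgf15, Hes3, Gbx2, Wnt7a, Abcg5, Aldh1a3, Inmt, Cdhr1, Neurog2, Wnt1 and Irx2). Without WT replicates 1, 2 and 3 and KO replicates 1, 3 and 4 the counts were 490, 147, 101, 102, 132 and 105.

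**Figure D3:**
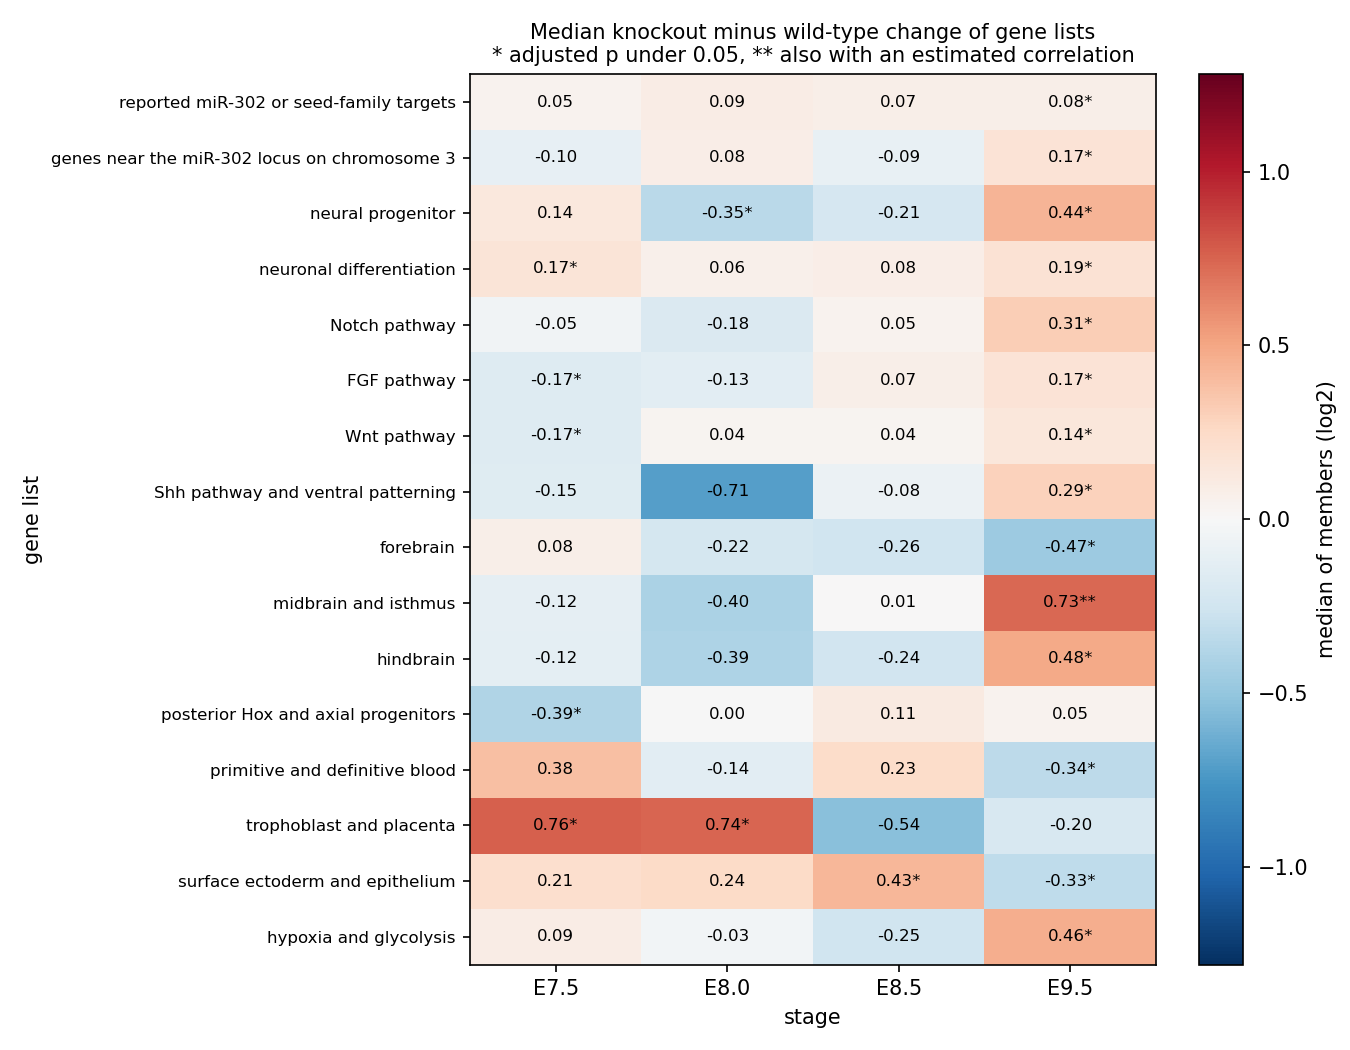
Median log2 difference between KO and WT of the 16 gene lists called at any stage, by stage, with * for a camera adjusted p under 0.05 and ** where it held with an estimated correlation. The midbrain and isthmus list at E9.5 (median 0.73) is the single one with **, and the forebrain list has a median of -0.47 there.

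The WT comparisons asked how anterior neural tissue changed with time. From E8.5 to E9.5 the neuropeptide gene Sst rose at least 9.39-fold (adjusted p = 6.75e-13), the neuronal transcription factor Neurod4 at least 7.88-fold (adjusted p = 4.41e-08) and the adhesion molecule Vcam1 23.3-fold (4.54, SE 0.52, adjusted p = 1.59e-06). Ptx3 and the platelet gene Pf4 rose at least 9.47-fold and 7.2-fold. Foxd4 fell at least 29.8-fold (adjusted p = 1.3e-07), and Egr2, a gene of hindbrain segments, fell too (-4.19, SE 0.309, adjusted p = 1.74e-08), with the stem cell gene Eras (-3.98), Krt23 (at least 9.15-fold) and the prolactin relative Prl2c3 (at least 9.67-fold). For Prl2c3 the E8.5 arrays lay far apart (SD 2.61 on the log2 scale). In all, 1944 genes rose and 2354 fell. Of 32 neuronal differentiation genes 21 rose and 1 fell (median 0.97, adjusted p = 1.35e-06, adjusted p = 0.0238 with an estimated correlation). Of 22 reported miR-302 or seed-family targets 10 rose and 2 fell (median 0.37, adjusted p = 0.0109, adjusted p = 0.0437 with an estimated correlation). Head and trunk mesenchyme genes (10 up and 1 down of 17, adjusted p = 0.000108), blood genes (8 up and 0 down of 13, adjusted p = 0.00242) and hindbrain genes (0 up and 6 down of 13, adjusted p = 0.0231) were also called. With an estimated correlation their adjusted p was 0.0934, 0.51 and 0.51. Stage and plate cannot be told apart here.

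From E8.0 to E9.5 in WT tissue 1974 genes rose and 2455 fell, led by Rnd3 (5.62, SE 0.874, adjusted p = 4.33e-05), Dlx1 (4.41), Sst (4.26), Ptx3 (4.22) and Gng5 (18.1-fold, adjusted p = 4.77e-08). Dlx1, Sst and Ptx3 were above background on 0 of the 2 E8.0 arrays, and their folds have no usable bound. The largest falls were Prl2c3 (at least 47.5-fold), Foxd4 (at least 41.4-fold), Prl2c4 (at least 32.9-fold), the atrial myosin gene Myl4 (-5.11, SE 0.764, adjusted p = 2.87e-05) and Rhox9 (at least 17.1-fold). The 2 E8.0 arrays lay far apart on the log2 scale for Prl2c3 (SD 2.28), Prl2c4 (SD 2.29), Myl4 (SD 1.89) and Rhox9 (SD 1.06). The sizes of these falls therefore rest on the mean of unlike arrays. Of 32 neuronal differentiation genes 18 rose and 2 fell (adjusted p = 7.84e-06, adjusted p = 0.0396 with an estimated correlation). Of the 22 reported targets 8 rose and 2 fell (adjusted p = 0.0488), a call lost with an estimated correlation (adjusted p = 0.146). The calls of mesenchyme, blood and neural crest genes as higher and of hindbrain and visceral endoderm genes as lower (adjusted p from 0.000581 to 0.0491) were lost too (adjusted p from 0.155 to 0.842). The E8.0 WT neural arrays were on plate 1 and the E8.5 WT arrays on plate 2, so stage and plate coincide in this comparison too. From E8.0 to E8.5 (n = 2 and 3) 4 genes rose and 0 fell, with 701 at unadjusted p under 0.05 (limma). They were Sdhd (1.75, SE 0.249, adjusted p = 0.00517), the growth cone gene Gap43 (1.68, SE 0.223, adjusted p = 0.0039), Kpnb1 (1.20, adjusted p = 0.0236) and Golt1b (1.05, adjusted p = 0.0198). Forebrain genes were called as higher (adjusted p = 0.00485) and cardiac, visceral endoderm and trophoblast genes as lower (adjusted p = 0.000148, 0.00485 and 0.0323), none with an estimated correlation (adjusted p from 0.812 to 0.843). The E8.0 WT arrays lay apart for cardiac genes (mean log2 signal 6.54 and 8.80) and visceral endoderm genes (6.78 and 7.38). The count of 4 genes was 72 with plate as a covariate and 2 without E8.5 WT replicate 2. Only the E7.5 and E8.0 KO groups had arrays on both plates, so the plate offset behind the 72 came from KO arrays and not from WT tissue.

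The size of the KO effect differed between E9.5 and E8.5 for 1038 genes, 444 with a higher and 594 with a lower value at E9.5. Fgf15 was among them (1.21, adjusted p = 0.0166), with more of a rise at E9.5. So were En1 (2.81, SE 0.547, adjusted p = 0.00644), Gbx2 (2.24, adjusted p = 0.000459), Hes5 (2.28, adjusted p = 0.0178) and Wnt1 (1.37, adjusted p = 0.00652). Rspo3 (-3.19, SE 0.441, adjusted p = 0.00119) and Stmn3 (-2.43, SE 0.452, adjusted p = 0.00529) had lost their E8.5 rise. For En2 (2.04, SE 0.786, adjusted p = 0.101), Neurog2 (-0.07, adjusted p = 0.932), Cdkn1a (-0.74, adjusted p = 0.131) and Wnt7a (-0.50, adjusted p = 0.384) no difference was called. Between E8.5 and E8.0 the effect differed for 13 genes and between E9.5 and E7.5, where the tissue differs too, for 27. The count of 1038 was 228 with plate as a covariate, and it was 407 without E8.5 WT replicate 1, 434 without E8.5 KO replicate 2, and 663, 490 and 676 without E9.5 WT replicates 3 and 4 and KO replicate 3.

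To ask whether KO tissue looked ahead of or behind WT tissue in development, the KO effect was set against the WT change between the neural stages that share no arrays with it. Across genes, which are not independent replicates, r was 0.259 at E8.0, 0.432 at E8.5 and -0.00118 at E9.5. In exact two-sided relabelling tests p was 0.2, 0.1 and 1 (0.3, 0.3 and 1 after Benjamini-Hochberg adjustment over the 3 tests). The smallest p that relabelling allows is 0.1 at E8.0 and E8.5, and 0.0286 at E9.5, so the first 2 tests could not reach 0.05. Within plate 2, with 1 KO array and the same WT arrays, the E8.5 value was 0.362.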

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

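The tests that set Fgf15 against isthmus, midbrain and progenitor genes were chosen only after the Fgf15 result was seen.

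In the E9.5 groups of 4 arrays, a single array lay far from the other 3 in 10 of 134 gene and group pairs, where chance gives about 1 in 20 pairs, and 7 of the 10 lay in WT replicate 4. Its log2 values were 7.32 for Celsr2 (others 8.71 to 8.78), 7.98 for Crmp1 (8.87 to 8.97), 8.47 for Fgfbp3 (9.22 to 9.34), 11.29 for Hk2 (11.83 to 11.93), 7.85 for Hoxa2 (9.23 to 9.27), 5.19 for Nkx2-9 (6.12 to 6.18) and 6.37 for Wnt7a (6.94 to 7.0). KO replicate 1 was at 13.25 for Gar1 (others 12.97 to 13.0) and 11.09 for Irx2 (10.81 to 10.84), and KO replicate 3 at 5.83 for Hes3 (7.15 to 7.40). Without WT replicate 4, 62 genes passed at E9.5 in place of 233. Of the genes for which it lay apart, Wnt7a kept its call, Celsr2, Fgfbp3, Hk2 and Nkx2-9 lost theirs, and Crmp1 and Hoxa2 had not passed.

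The KO effect differed between E8.5 and E8.0 for 13 genes in tests of the difference itself. The KO minus WT value was more positive at E8.5 for Wnt7a (2.24, adjusted p = 0.0322), the imprinted gene Dlk1 (1.77, adjusted p = 0.0458), Cyp1b1 (1.74, adjusted p = 0.0485) and Rmnd5a (1.52, adjusted p = 0.0238). It was more negative for Bhlha15 (-2.24, adjusted p = 0.0483), the bone gene Sp7 (-1.97, adjusted p = 0.0238), Mmp19 (-1.96, adjusted p = 0.0455), Rinl (-1.90, adjusted p = 0.0322) and Hand1 (-1.74, adjusted p = 0.0483). Wnt7a was above background on 0 arrays of the E8.0 comparison and Hand1 on 0 at E8.5, so their differences largely restate the change at the other stage. Cyp1b1 and Rmnd5a were above background on 1 and 2 arrays at E8.0, and Mmp19 on 1 at E8.5. Their values there (-0.774, -0.619 and -0.62) made up a part of the difference but came mostly from arrays without detection. The count was 0 without E8.0 WT replicate 2 or E8.5 WT replicate 1, 1 and 2 without E8.0 WT replicate 3 and KO replicate 1, and 26 without E8.0 KO replicate 3. It was 6, 62, 4 and 6 without E8.5 WT replicate 3 and KO replicates 1, 2 and 3.

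Between E9.5 and E8.5 the effect differed for 1038 genes. The highest number in other splits of the arrays within both stages, of 100 drawn with the real one included, was 154. Only 1 split, the real one, reached 1038, a share under 0.05. These splits take the KO effect out of both stages, so they do not test an equal effect at both. Nor do they separate plate 3, which held KO replicates 2 and 3 of E8.5. The difference was positive for Foxd4 (3.64, adjusted p = 0.00534), En1 (2.81, adjusted p = 0.00644), Pfkp (2.64, adjusted p = 0.0302), Irx1 (2.45, adjusted p = 0.0114) and Sema4f (2.44, adjusted p = 0.00955). Foxd4 and Sema4f were above background on 1 and 2 of the 8 arrays at E9.5, so their differences largely restate the E8.5 falls. The difference was negative for Rspo3 (-3.19, adjusted p = 0.00119), H2bc8 (-2.97, adjusted p = 0.0029), Myl1 (-2.88, adjusted p = 0.0115), Stmn3 (-2.43, adjusted p = 0.00529) and Rpl22l1 (-2.41, adjusted p = 0.019). The count was 407 without E8.5 WT replicate 1, 434 without E8.5 KO replicate 2, and 663, 490 and 676 without E9.5 WT replicates 3 and 4 and KO replicate 3. Between E9.5 and E7.5, where the tissue differs as well, 27 genes differed. The difference was positive for Sox21 (2.07), Gbx2 (2.06), Fgf15 (1.84), Dll1 (1.80) and Lgr5 (1.56), and negative for Scg5 (-2.51), Cavin3 (-1.86), Ugt8a (-1.83), Mterf2 (-1.81) and Bcl11a (-1.81), with adjusted p from 0.00458 to 0.0378. Lgr5 was above background on 1 of the 8 arrays at E9.5 and 2 of 5 at E7.5, so its difference largely restates the E7.5 fall. That count was 53, 6, 10 and 2 without E7.5 WT replicates 1 and 2 and KO replicates 1 and 2, and 4, 2, 3, 3 and 11 without E9.5 WT replicates 2 and 4 and KO replicates 1, 2 and 3.

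Of the larger counts in the report, that at E9.5 (233 genes) was reached by 1 of 35 splits of the 8 arrays, the real one, with 12 genes in the highest other split. That share is under 0.05 and the smallest these splits allow, so a chance split of the arrays is unlikely to give that count. For the 14 lists called at E9.5, 2 of 35 splits reached as many, with 14 in the highest other, so chance cannot be excluded for that number of lists. For the 574 genes at E8.5 (highest other split 7, with 1 of 10 splits reaching 574), the splits are too few for a share under 0.05. For the 1 list there, 9 of 10 splits reached 1, with 8 in the highest other, so chance cannot be excluded for that list. For the 4298 genes that changed in WT tissue from E8.5 to E9.5, 1 of 35 splits, the real one, reached as many, so a chance split is unlikely to give that count. The highest other split called 2899 genes. Some splits set all but 1 of the E9.5 arrays against the E8.5 arrays joined by that 1 array. Such splits keep most of the stage difference, so a high count in them need not mean another structure of the samples. These stages also lay on different plates.

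Fgf15 was higher in KO tissue at E8.5 and E9.5, and a KO dissection with more isthmus and midbrain tissue could raise it, as could a lower share of blood and surface ectoderm. At E8.5 the first was argued against, since the other 10 genes of the isthmus and midbrain list had a median of -0.075 (SE 0.2), below 0.461, which is 0.5 of the Fgf15 change. Each SE in this paragraph comes from resampling the genes of a list. It treats genes as independent and leaves out the spread between embryos, so these arguments are tentative. A lower share of blood and surface ectoderm was only weakly argued against at E9.5 as the whole cause. The 23 progenitor genes had a median of 0.372 (SE 0.182) against a bound of 1.06. Forebrain genes are in that list too, Six3 among them, which fell at E9.5. The median may therefore understate how far a higher neural share would raise a midbrain gene. The Hes genes of that list had been left out, although Hes5 and Hes3 were among the largest rises. With them in, the median of the 26 genes was 0.44. More isthmus and midbrain tissue at E9.5 stays open, since the other 10 genes had a median of 0.715 (SE 0.41, 8 above 0), too wide a spread to part it from 1.06, and the E9.5 rise of En1 and Wnt1 cannot be told apart from it. A change of Fgf15 in the same cells after loss of miR-302 stays open too and was not tested.

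The E8.5 changes could come from a signal difference of plate 3, which held KO replicates 2 and 3, or from tissue at another point of development. Genes called from the plate 3 arrays were measured on plate 2, between KO replicate 1 and a left-out WT array, where their median signed difference was 0.453, 0.299 and 0.255 of the size on the calling arrays in 3 rotations (68.6 to 75.2% in the same direction), between the bounds of 0.25 and 0.5 set for the test. A part of the changes thus stands on plate 2 as well, and how much plate 3 adds stays open. The correlation with the WT change from E8.0 to E9.5 was 0.362 within plate 2, from 1 KO array, 0.382 for the plate 3 KO arrays and 0.432 in all, and as these share the 3 WT arrays they are not separate evidence. A difference in development stays open, because another relabelling of the arrays gave 0.431 and the exact two-sided p of 0.1 is the smallest the design allows.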

How the results depend on the processing

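The series matrix identities of the E8.0 WT arrays, the whole-embryo array added without KO replicate 1, and the separate normalization of E9.5 were chosen after seeing the data. Over all alternatives, 4890 values of named genes were compared with the reported ones. Of these, 3740 kept their side of the threshold, 3707 with the same sign and 33 that passed in neither setting with the other sign. Of the rest 1025 no longer passed and 125 newly passed, and 0 values that passed in either setting turned direction. Of 1798 values of lists 1673 kept their side, 99 of them called in neither setting and with the other direction, 66 were no longer called and 59 were newly called, and 0 called in either setting turned direction. At E9.5, Fgf15 (1.80 to 2.25), En1 (1.37 to 2.88), Gbx2 (1.52 to 1.93), Hes5 (1.72 to 2.33) and Neurog2 (0.66 to 1.61) passed in all 22 alternatives, with 0.0381 as the highest adjusted p, and En2 in 19. These alternatives did not include single probes, and the other Neurog2 probe did not rise at E9.5. At E8.5, Fgf15 passed in 13 of 21, Cdkn1a in 17 and Neurog2 in 18. At E8.0, Ccng1 passed in 18 of 23 and Hand1 in 11, and at E7.5 Bcl11a passed in 17 of 20. Signal over background limits the genes tested: Larp7, Lats2, Lefty1 and Pax6 were not tested. The strict filter, with detection p under 0.01 and counted within each group rather than over all arrays, kept 13221 probes in place of 15030. Replicate numbers did not pair embryos (correlations of -0.135 to 0.161 between samples of the same number). The planned search for miR-302 sites in transcripts was not run, as transcript sequences were not used here. For the results below that moved, the cause was not tested, except that fewer arrays enter where some are left out.

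Counts of genes are given for KO against WT by stage, for WT E8.5 against E8.0 (WT pair), and for differences of the KO effect between E8.5 and E8.0 (early), E9.5 and E8.5 (late) and E9.5 and E7.5 (long). Reported counts were 23, 178, 574 and 233 for E7.5, E8.0, E8.5 and E9.5, 4 for the WT pair, and 13, 1038 and 27 for early, late and long, with 5, 2, 1 and 14 lists and correlations of 0.259, 0.432 and -0.00118. Quantile normalization of raw log2 signals gave 9 at E7.5, 355 at E9.5, 0 for the WT pair, 0 early, 1 list at E8.0, and r of 0.368 at E8.0 and 0.511 at E8.5. The authors' series matrix values gave 6 at E7.5, 16 at E8.0 (7 higher, 9 lower), 610 at E9.5 (340 higher, 270 lower), 1 for the WT pair, 0 early, 0 lists at E8.0 and r of 0.11 at E9.5. Median scaling gave 4 at E7.5, 109 at E8.0 (94 higher, 15 lower), 415 at E9.5, 0 for the WT pair, 0 early, 4 lists at E8.0, 2 at E8.5, and r of 0.342 at E8.5 and 0.0719 at E9.5. With E9.5 arrays normalized separately, there were 9 at E7.5, 518 at E9.5, 1 list at E8.0 and 3 at E8.5. No probe filter gave 44 at E7.5, 7 for the WT pair, and 1, 1 and 0 lists at E7.5, E8.0 and E8.5. The strict filter gave 5 early, 42 long and 0 lists at E8.5. All probes gave 7 early, and the mean of probes 7 early.

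Plate as a fixed covariate gave 53 at E8.0, 99 at E8.5, 383 at E9.5, 72 for the WT pair, 3 early, 228 late, 2 long and r of 0.362 at E8.5. Plate as a random block (correlation 0.246) gave 223 at E8.5, 2 for the WT pair, 4 early, 3 lists at E7.5, 0 at E8.5, and r of 0.306 at E8.0 and 0.136 at E9.5. Within 1 plate there were 170 at E8.5, and 2 lists at E7.5 and 2 at E8.5. Each stage fitted alone (limma) gave 0 at E7.5, 0 at E8.0, 0 at E8.5 and 449 at E9.5, against 23, 178, 574 and 233 in the shared fit. It gave 9 lists at E7.5 and 2 at E8.5. In the shared fit 817, 2039, 2360 and 1850 genes had an unadjusted p under 0.05. Array weights gave 7 at E7.5, 665 at E8.0, 1172 at E8.5, 1588 at E9.5, 31 for the WT pair, 54 early, 1947 late, 6 long and r of 0.349 at E8.5. The eBayes fit with trend and robust gave 365 at E9.5 and 0 early. A replicate block gave 14 at E7.5, 0 at E8.0, 0 early, 624 late and 2 long. With plate added to that block, there were 111 at E7.5, 54 at E8.0, 23 at E8.5, 1 early, 30 late, and 2 lists at E7.5 and 3 at E8.5. Including the E8.0 whole-embryo array gave 31 at E8.0, 0 for the WT pair and 4 early. With that array as the series matrix identifies it, there were 4 at E8.0, 2 for the WT pair, 1 early and 5 lists at E8.0. With the array included and E8.0 KO replicate 1 left out, there were 6 at E8.0 and 4 lists.

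An adjusted p under 0.1 gave 37, 518, 1171 and 509 genes at the 4 stages, 11 for the WT pair, and 24 early, 1780 late and 68 long. Camera with an estimated correlation called 0, 0, 0 and 1 lists, and fry 0, 0, 0 and 11. Lists without shared genes gave 0 at E8.5 and 9 at E9.5. Over genes that differ between WT stages r was 0.416, 0.589 and -0.496, the last over 4 genes. Scaling also moved the balance of rises and falls: median scaling gave 330 and 152 at E8.5, 1702 and 4393 for WT E9.5 against E8.5, 1598 and 4688 against E8.0, and 357 and 784 late. Without each array in turn, counts ranged from 11 to 60 at E7.5, 0 to 695 at E8.0, 110 to 729 at E8.5 and 62 to 490 at E9.5, 0 to 4 for the WT pair, 3564 to 4222 for WT E9.5 against E8.5, 3202 to 4359 against E8.0, 0 to 62 early, 407 to 1303 late and 2 to 53 long. Lists ranged from 2 to 6, 1 to 7, 0 to 2 and 10 to 14, and r from 0.209 to 0.311, 0.371 to 0.48 and -0.0103 to 0.025. Where 1 WT array remained, it was assumed to vary like the other groups. The lowest and highest counts came at E7.5 without KO replicate 1 and WT replicate 1, at E8.0 without WT replicate 2 and KO replicate 3, at E8.5 without WT replicate 1 and KO replicate 1, and at E9.5 without WT replicates 4 and 1.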

Other observations

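The mean of the KO effect over the 4 stages and the tests of reported targets and of genes near the miR-302 locus in it were chosen only after the results by stage were seen.

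In the mean of the 4 KO minus WT contrasts, 212 genes were higher and 129 lower, 186 of them with the same sign at each stage. Fgf15 was 1.06 higher (SE 0.114, adjusted p = 3.5e-05), and Cdkn1a 0.81 (SE 0.122, adjusted p = 0.00156). Other rises were the thiamine triphosphatase Thtpa (0.50, SE 0.0493, adjusted p = 3.34e-05), Zkscan1 (0.60, SE 0.0634), Ly6h (1.15, SE 0.123), Stmn3 (1.26, adjusted p = 0.000961), Ccng1 (0.92, adjusted p = 0.000294) and the reported target Dazap2 (0.81, SE 0.12, adjusted p = 0.00149). Stmn3 (-0.01) and Ccng1 (-0.20) had no rise at E9.5. The E9.5 values of Thtpa (0.10), Zkscan1 (0.16) and Dazap2 (0.16) were small, so their mean came mostly from the earlier stages. Fgf15 (2.13), Ly6h (0.95) and Cdkn1a (0.70) had larger values at E9.5. Cited2, a transcription cofactor needed for neural tube closure, was lower (-0.66, adjusted p = 0.00156), as was Abcg5 (-0.78, adjusted p = 0.00168). At E9.5 their values were -0.13 and -1.52. With plate as a covariate 107 and 78 genes passed, 135 of these in both fits, and Fgf15 was at 1.05 (adjusted p = 0.00103). Neuronal differentiation genes were higher as a set (median 0.12, adjusted p = 0.0119, adjusted p = 0.25 with an estimated correlation) and forebrain genes lower (median -0.34, adjusted p = 0.0259, adjusted p = 0.966 with an estimated correlation). With plate as a covariate the neuronal list was still called (adjusted p = 0.00539) and the forebrain list was not (adjusted p = 0.246).

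At E8.0 and E8.5, 37 genes rose at both stages, where 3.91 would be expected by chance, 12 fell at both (1.33 expected), and 2 genes passed in opposite directions. The correlation of the KO effects across genes was 0.338. At both stages some KO arrays lay on another plate than the WT arrays of the comparison. A part of this overlap that comes from the plates was not told apart from a shared KO effect. At E8.5 and E9.5, 9 genes rose at both (5.08 expected), namely Fgf15, Neurog2, Wnt7a, Fgfbp3, Etv4, Ckb, Aldh5a1, Ly6h and Tle5, and 5 fell (1.76 expected), namely Abcg5, Cdhr1, Mip, Actn3 and Tnnt1. As many passed in opposite directions there, with 8 genes higher at E8.5 and lower at E9.5 and 6 the other way, and the correlation across genes was -0.17. At E8.0 and E9.5, 0 genes rose at both (1.92 expected) and 0 fell at both (0.391 expected). There 1 gene was higher at E8.0 and lower at E9.5 and 4 went the other way, with a correlation of -0.244. Those expected numbers treat genes as independent, which they are not.

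Loss of miR-302 could raise its reported targets in the mean of the 4 stages. The list of 22 targets had a median of 0.04 and was not called, with a camera p of 0.0141, and 0.0157 with an estimated correlation (0.136 and 0.25 adjusted over the lists), and the list includes Fgf15, known from study of such mice. Without Fgf15 the p-values were 0.0751 and 0.069, and without Fgf15, Cdkn1a and Dazap2, the top members, 0.567 and 0.543, a rise that leaving out top members brings by construction. The explanation stays open. Of the members Fgf15, Cdkn1a, Dazap2 and Casp2 (0.37, adjusted p = 0.0074) passed as higher and Arid4b (-0.50, adjusted p = 0.031) as lower. A strain or targeting difference around the miR-302 locus could also move genes near it, such as Neurog2 (0.76, SE 0.142, adjusted p = 0.00657) and Ugt8a (0.67, SE 0.123, adjusted p = 0.00583), the only members of 11 that passed. The fry mixed p of the 11 genes was 3.78e-05, but their absolute limma statistics were not shown to rank above those of other genes (median 1.43 against 1.08, permutation p = 0.289), so that stays open as well.

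The E8.0 WT array labelled as a whole embryo had a mean log2 signal of 5.66 for posterior Hox genes, against 5.61 and 5.84 on the other E8.0 WT arrays and 7.85 and 8.46 on the E7.5 WT arrays. For visceral endoderm genes it was at 6.74, against 6.78 and 7.38, and 10.76 and 9.94. For cardiac genes it was at 6.89, against 6.54 and 8.80, and 8.20 and 8.08. For trophoblast and placenta genes it was at 9.22, against 8.40 and 7.88, and 7.74 and 7.41, with 8.72 to 9.5 on the E8.0 KO arrays. For neural progenitor genes it was at 8.09, against 8.09 and 8.06, and 6.77 and 7.0.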
